A study of Mus musculus with 8 samples.

How the data were processed

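The deposited table held, per the file headers, gene counts for 8 libraries, 4 from SPF and 4 from germ-free mice, for 22911 genes. Per the submitters' processing notes the upstream tools were bcl2fastq 2.18.0.12, cutadapt 1.18, TopHat2 2.1.1, HTSeq 0.6.0 and DESeq2 1.22.2 on GRCm38, with no role or order given. The lowest sum over the 8 libraries was 10 counts. The deposited counts were raw whole numbers from a library kit for total RNA with ribosomal RNA depletion. The strand setting of the counting is not given in the sources used here, so genes that overlap or have antisense transcripts are uncertain. The authors' normalized values, per the file headers, were counts divided by 1 DESeq2 size factor per library. The authors' baseMean column was the mean of those normalized signals over the 8 libraries. The deposited log2 fold changes and their standard errors were those of SPF over germ-free from the authors' DESeq2 run. The deposited score column was the Wald statistic from that run. The deposited p-values and Benjamini-Hochberg adjusted p-values covered 22819 genes, and 92 genes had none.

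The comparison used the deposited counts, and directions are germ-free minus SPF. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15, smallest group 4), which left 15098. Counts were scaled by TMM and tested with glmQLFit (robust) and the two-sided quasi-likelihood F test with group as the only term. A gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken from the F statistic, and fold changes were fitted with a prior count of 0.125. CPM values were scaled by TMM, and 1 count was added before log2. Values listed as not called had no call by this test. The median log2 fold change of all tested genes was 0.0209, and the median SE of the called genes was 0.138. Coordinates are those of the deposited table, and 99.2% of identifiers shared start and end with the GENCODE M21 annotation. Close paralogs share reads, so values for class I, serpin, Sprr2a, histone and ribosomal protein genes are less certain. Intervals and floors cover counting error only.

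Before the data were examined 43 gene lists, the test, the alternatives to it and the rule for naming genes were fixed. The rule named the 12 largest rises and the 12 largest falls among called genes with a mean of at least 2 CPM in a group and no overlap between the groups, leaving out predicted or unnamed models and sex-linked genes. It also named the 4 members with the smallest unadjusted p in each list and the sex-linked genes as a check of the animals. This gave 165 genes, of which 63 were called. Genes named beside these, and the families of mitotic, helicase and histone genes, were chosen after their values were seen. Lists with at least 5 tested genes, 34 in all, were tested with limma's camera on voom values at a preset correlation of 0.01. At an adjusted p under 0.05 it called 20, of which 7 were higher and 13 lower. With an estimated correlation 0 were called, 5 had an unadjusted p under 0.05 and the smallest adjusted p was 0.125. The fry rotation test called 6 lists by its directional p, which tests whether the genes of a list move on balance one way. It called 22 by its mixed p, which tests for change in either direction. Neither compares a list with other genes. The sex-linked list was left out of these tests.

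The procedure was tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold among 15098. edgeR recovered 61 and 75 of them and called 2 unchanged genes, and DESeq2 recovered 65 and 81 and called 20. The median fitted log2 fold changes by edgeR were 1.04 and 1.96. With 20 genes of a simulated list shifted by 0.5, camera gave an adjusted p of 3.12e-16 and called 1 other list, camera with an estimated correlation gave 0.00284 and fry 0.0101, with no other list called. Each gene was simulated independently, so the simulated lists held no correlation between genes. The simulation therefore does not measure false list calls where the genes of a list vary together.

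The fits were repeated with DESeq2 size factors, upper-quartile factors, the DESeq2 Wald test, limma voom with quality weights, other filters, a replicate block, and each library left out. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Reads were not used here. The values of 1 named gene are not reported here.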

Results

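RNA was sequenced from buccal epithelial cells of adult C57BL/6 mice, an inbred laboratory strain. Germ-free mice, which carry no microorganisms, were compared with specific pathogen-free (SPF) mice, which carry a resident microbiota without listed pathogens. Each group held 4 animals and gave 1 library per animal, so n = 4 for every mean and standard deviation (SD) below. The comparison addresses how gene expression in the oral epithelium differs between mice with and without resident microbes. Gene counts summed to 10260264, 14730960, 13181875 and 13549361 in SPF libraries 1, 3, 4 and 5, and to 13783866, 15170813, 15524731 and 10430507 in germ-free libraries 1 to 4. The basal keratin gene Krt5 was at 12554 CPM (counts scaled to library size) in SPF and 11952 CPM in germ-free libraries. Xist, transcribed from the inactive X chromosome, lay between 2024 and 3304 CPM in the 8 libraries, and the Y-linked Kdm5d did not exceed 1.02 CPM in any of them.

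Oral epithelium of germ-free mice carried more RNA of circadian repressors and clock output genes, and less RNA of mitotic genes, of glycolytic enzymes and of several epithelial immune genes, than that of SPF mice. The clock repressor Bhlhe41 was 6.90-fold higher and the glucose transporter gene Slc2a1 2.20-fold lower in the germ-free group. Of 15098 genes tested, 631 were called at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 279 higher and 352 lower in germ-free libraries. Among these, 83 rose and 106 fell by at least 1 on the log2 scale. The groups did not overlap for 607 of the 631 genes, and for 13.1% of all tested genes, where chance gives 2.86%. The authors' deposited results called 1190 genes, 600 higher in SPF and 590 higher in germ-free mice, and 630 of the 631 genes were among them with the same direction. The number of calls fell to 284 without SPF 3, 301 without SPF 4, 318 without SPF 5, 379 without germ-free 3 and 286 without germ-free 4, and was 1257 by DESeq2 and 1023 by limma voom with quality weights. It was 12 with a score of stromal RNA as a covariate, a score that itself differed between the groups.

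**Figure D1:**
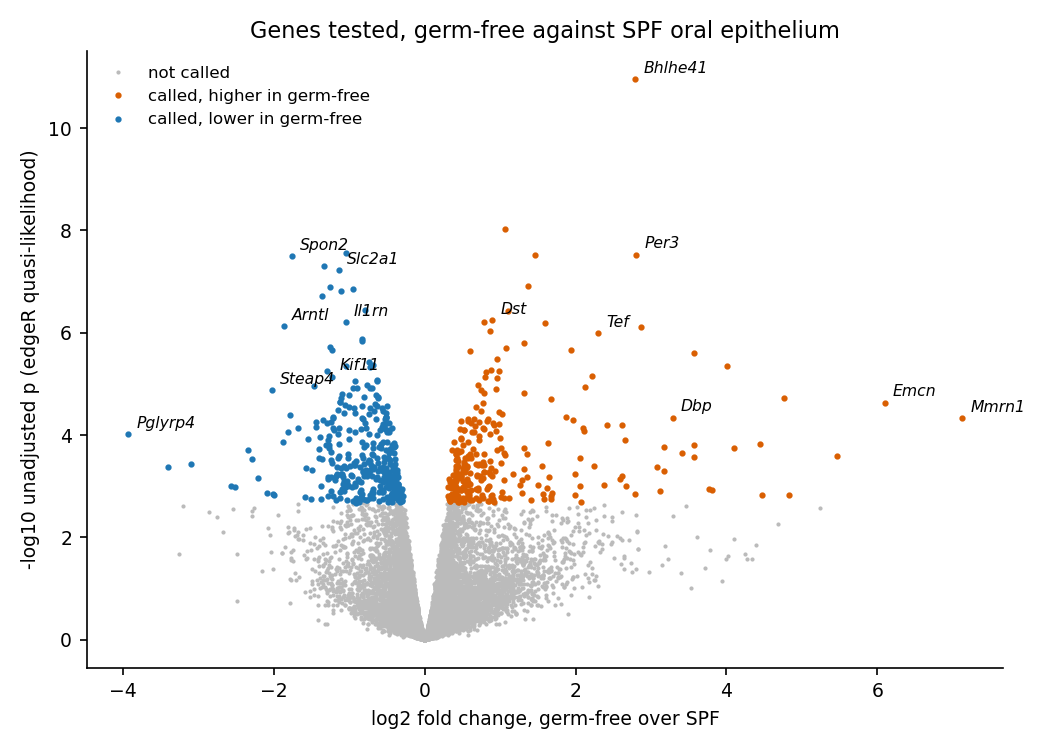
Each point is 1 of the 15098 genes tested, with the log2 fold change of germ-free over SPF on the x axis and −log10 of the unadjusted p on the y axis. The 279 genes called higher in germ-free libraries are orange and the 352 called lower are blue; Bhlhe41 has the smallest p.

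Repressors and output genes of the circadian clock were higher in germ-free libraries and its activators lower. Of 20 tested clock genes 10 rose and 3 fell in germ-free libraries, and 13 rose and 3 fell when adjusted over the list alone. The list was higher by camera (median log2 fold change 0.65, adjusted p = 6.27e-07; adjusted p = 0.1254 with an estimated correlation), and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, gave an adjusted p of 0.000891. The 3 genes that fell encode the activating arm of the clock. Arntl, which encodes BMAL1 (ENSMUSG00000055116, GRCm38 chromosome 7, 113207465 to 113314126, plus strand), fell from 100.2 ± 13.01 to 27.4 ± 7.74 CPM (mean ± SD), a log2 fold change of −1.87 ± 0.19 (standard error, SE; adjusted p = 0.000552). Npas2 fell by 1.44 and Clock by 0.73 on the log2 scale. The genes that rose encode repressors and output factors that the activating arm drives. Bhlhe41 (ENSMUSG00000030256, chromosome 6, 145858243 to 145865558, minus strand) rose from 9.41 ± 1.59 to 64.9 ± 5.34 CPM (log2 fold change 2.79 ± 0.14, adjusted p = 1.65e-07). Per3 (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665, minus strand) rose from 20.7 ± 4.98 to 144 ± 30.0 CPM (2.81 ± 0.19, adjusted p = 8.09e-05). Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203, plus strand), an output transcription factor, rose 9.76-fold, from 31.0 ± 15.1 to 300.2 ± 55.8 CPM (3.29 ± 0.36, adjusted p = 0.00667). Nr1d2, which encodes the repressor REV-ERBβ, rose by 1.37 ± 0.13. Per2 (2.67), Ciart (2.61), Tef (2.29), Cry2 (1.02), Hlf (0.68) and Nr1d1 (0.62) also rose on the log2 scale. Per1 was at 188 CPM in SPF and 192 CPM in germ-free libraries, and Cry1 at 15.1 and 11.2 CPM, and neither passed the test. The clock genes beyond the 4 with the smallest p were picked for naming after their values were seen, as were further members of the lists below. With any 1 library left out, 7 to 10 clock genes rose, 7 of them without SPF 5, and 3 fell. The Cry2 call ended without SPF 5, the Nr1d1 call without any library other than SPF 1, and the Per2 call without any library other than SPF 1 and germ-free 2. With the stromal score as covariate Bhlhe41 and Per3 rose and 0 genes fell. For the other 11 the median absolute log2 fold change went from 1.44 to 1.25 and the median SE from 0.186 to 0.305, and 11 had an unadjusted p under 0.05. The hour at which tissue was taken is not given in the sources used here. A difference in hour between the groups therefore cannot be told apart from a group difference, for these genes or for those below. The labels give no batch either, and a batch or other condition that followed the groups would look the same.

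**Figure D2:**
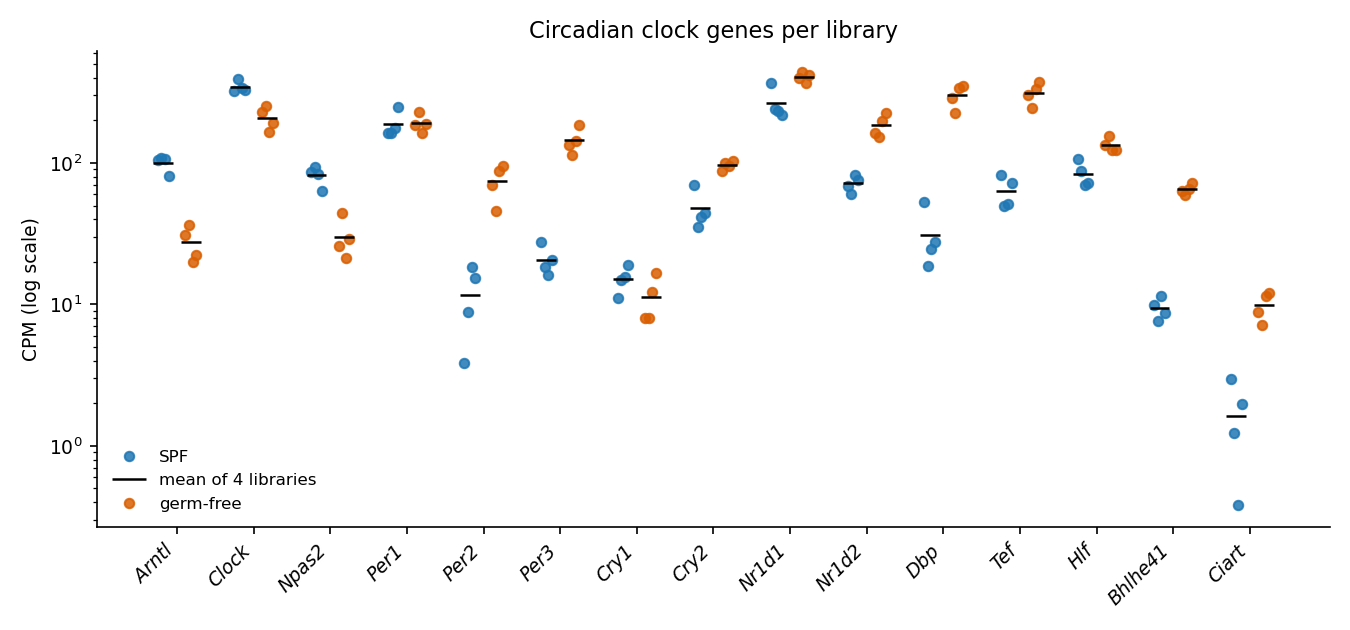
CPM of 15 clock genes on a log axis in each of the 4 SPF (blue) and 4 germ-free (orange) libraries, with black bars at the mean of each group. Arntl, Clock and Npas2 lie lower in all germ-free libraries, while Bhlhe41, Per2, Per3, Dbp and Tef lie higher in all of them.

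Genes of mitosis were lower in germ-free epithelium, while 2 genes of the replicative helicase were higher. Of 40 tested cell cycle genes 17 fell and 2 rose by edgeR (26 and 6 when adjusted over the list alone). DESeq2 called 25 lower and 5 higher, and limma voom 26 lower and 5 higher. The list was lower by camera (median −0.93, adjusted p = 1.13e-09; adjusted p = 0.262 with an estimated correlation), and fry gave 0.0241. Kif11, a spindle motor (ENSMUSG00000012443, chromosome 19, 37376403 to 37421859, plus strand), fell from 145 ± 21.2 to 61.6 ± 13.6 CPM (−1.23 ± 0.16, adjusted p = 0.00247). The spindle assembly factor gene Tpx2 fell from 163 ± 22.6 to 70.1 ± 18.0 CPM and the checkpoint kinase gene Bub1b by 1.27 ± 0.20. Mki67, which encodes the proliferation antigen Ki-67, fell from 1648 ± 133 to 765 ± 251 CPM. E2f8, a repressor of E2F target genes, fell by 0.60 ± 0.12, and Rrm1, a subunit of ribonucleotide reductase, by 0.48 ± 0.10. The 2 genes that rose by edgeR were the helicase subunits Mcm2 (0.85 ± 0.18) and Mcm6 (0.79 ± 0.15). Sapcd2, a regulator of spindle orientation, and Ankle1, a DNA endonuclease, were among the 12 genes with the largest falls, at −1.78 ± 0.30 and −1.68 ± 0.30. The number of cell cycle genes that fell was 4 without SPF 3 or SPF 4, 8 without SPF 5 and 10 without germ-free 4, and the number that rose was 1 without SPF 3, SPF 4, germ-free 3 or germ-free 4 and 4 without germ-free 1 or germ-free 2. The E2f8 call ended without SPF 3 or SPF 4, the Mki67 call without any SPF library or germ-free 2, and the Rrm1 call without SPF 3, SPF 4, SPF 5 or germ-free 4. The Mcm2 call ended without SPF 4, germ-free 3 or germ-free 4, and the Mcm6 call without SPF 3. With the stromal score as covariate edgeR called 0 of the 19, 17 had an unadjusted p under 0.05, the median absolute log2 fold change went from 1.12 to 0.86 and the median SE from 0.212 to 0.311. The Sapcd2 and Ankle1 calls ended with it too.

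**Figure D3:**
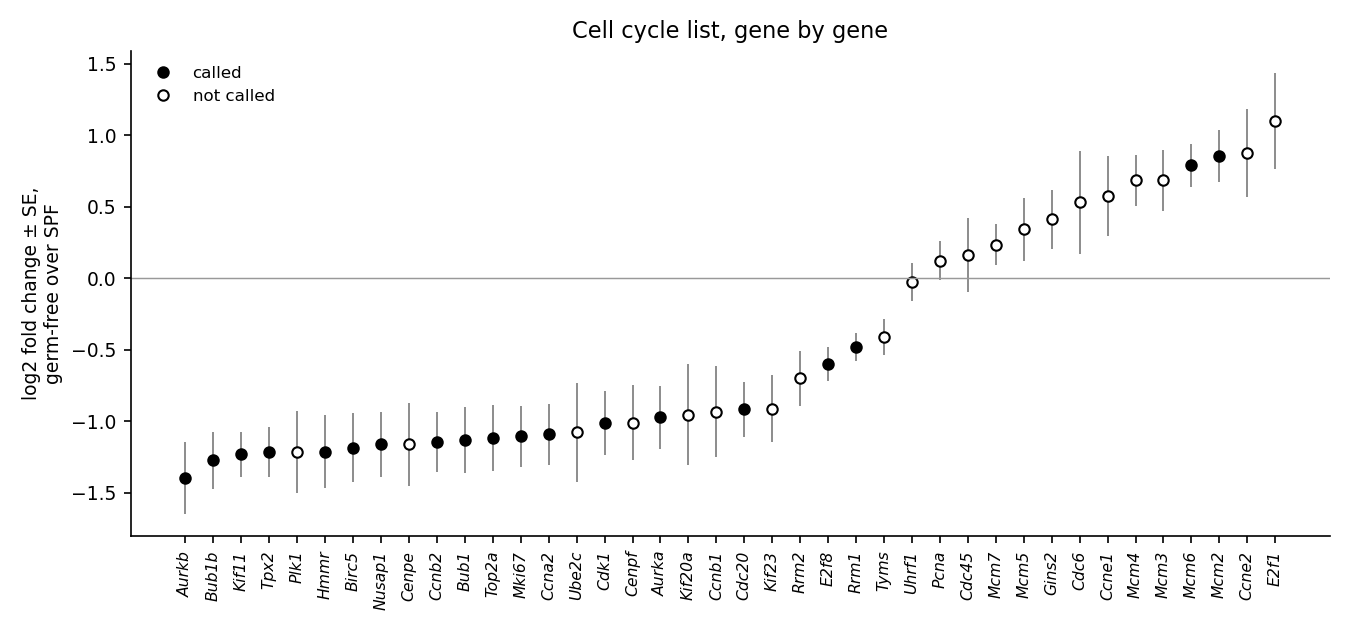
Log2 fold change of germ-free over SPF for each of the 40 tested genes of the cell cycle list, ordered by size, with bars of 1 SE and filled circles for genes called. The 17 filled circles below 0 are mostly mitotic genes, and the 2 above 0 are Mcm2 and Mcm6.

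Genes of glucose uptake and glycolysis were lower in germ-free libraries. Of 18 tested members 8 fell and 0 rose (10 fell when adjusted over the list alone), and the list was lower by camera (median −0.37, adjusted p = 4.83e-09; adjusted p = 0.1254 with an estimated correlation; fry 0.00211). Slc2a1, which encodes the glucose transporter GLUT1 (ENSMUSG00000028645, chromosome 4, 119108711 to 119137983, plus strand), fell from 348 ± 47.1 to 158 ± 16.4 CPM (−1.14 ± 0.11, adjusted p = 0.000111). The glycolytic enzyme genes Pfkp (−0.62 ± 0.10), Pgam1 (−0.53 ± 0.09), Tpi1 (−0.52 ± 0.09), Eno1 (−0.50 ± 0.09), Gapdh (−0.41 ± 0.10), Pgk1 (−0.41 ± 0.10) and Pkm (−0.33 ± 0.09) fell by less. Without SPF 3, SPF 4, SPF 5, germ-free 2, germ-free 3 or germ-free 4, 5 of these genes passed, and the Pgk1 and Pkm calls ended without each of these libraries. The Gapdh call ended without any library other than germ-free 1. Under the stromal covariate edgeR called 0 of the 8, 7 had an unadjusted p under 0.05, the median absolute log2 fold change went from 0.51 to 0.50 and the median SE from 0.0945 to 0.157. Of 33 nuclear genes of the respiratory chain 1 fell by edgeR, Cox5b (−0.41 ± 0.10; 4 fell when adjusted over the list alone), and 32 had a log2 fold change below 0 (median −0.20, camera adjusted p = 3.05e-08; adjusted p = 0.262 with an estimated correlation; fry 0.0416). DESeq2 and limma voom each called 4 respiratory chain genes lower. In fatty acid and epidermal lipid synthesis 4 of 31 genes fell (6 when adjusted over the list alone). These were the ceramide synthase gene Cers3 (−0.89 ± 0.14), the acetyl-CoA carboxylase gene Acaca (−0.51 ± 0.10), Fabp5, a fatty acid-binding protein of keratinocytes (−0.57 ± 0.14), and the lipase-family gene Pnpla1 (−1.59 ± 0.40). The falls numbered 1 without germ-free 4 and 2 without SPF 1, SPF 4, SPF 5 or germ-free 1. The Acaca call ended without SPF 3 or germ-free 4, those of Fabp5 and Pnpla1 without SPF 1, SPF 4, SPF 5, germ-free 1, germ-free 2 or germ-free 4, and the Cox5b call without any library other than SPF 1 and germ-free 1. Without germ-free 1, 3 respiratory chain genes fell. The stromal covariate ended these 5 calls in edgeR, with 5 at an unadjusted p under 0.05, as the SE of Cox5b went from 0.0979 to 0.162 and the median SE of the 4 lipid genes from 0.136 to 0.229. The lipid list was lower by camera (median −0.13, adjusted p = 0.0126; adjusted p = 0.262 with an estimated correlation, fry 0.0676). Cholesterol synthesis was lower by camera (median −0.18, adjusted p = 0.0126; adjusted p = 0.588 with an estimated correlation, fry 0.27), a camera call lost without SPF 5 or germ-free 2. In it 0 of 20 genes were called by edgeR, DESeq2 or limma voom or over the list alone, and 2 had an unadjusted p under 0.05 (1 without SPF 4, germ-free 1 or germ-free 2, 0 without SPF 5).

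Genes that present peptides on MHC class I were lower in germ-free libraries as a list. All 20 tested members had a log2 fold change below 0 (median −0.80, camera adjusted p = 3.87e-12; adjusted p = 0.262 with an estimated correlation; fry 0.0703). Among them 2 fell when adjusted over all genes and 15 when adjusted over the list alone. H2-D1, a classical class I heavy chain (ENSMUSG00000073411, chromosome 17, 35262730 to 35267499, plus strand), fell from 614 ± 90.7 to 347 ± 91.7 CPM (−0.82 ± 0.19, adjusted p = 0.0406), and the proteasome activator gene Psme2 fell by 0.50 ± 0.11. Class I heavy chains are close paralogs, and reads shared between them make single-gene values uncertain. H2-K1 was at 615 ± 147 and 317 ± 110 CPM and B2m, the light chain, at 410 ± 139 and 189 ± 101 CPM, and neither passed. The 2 calls were lost without SPF 3, SPF 4, germ-free 3 or germ-free 4, 1 was left without SPF 5, and 5 were made without germ-free 1. DESeq2 called 13 of the 20 and limma voom 7. H2-D1 itself was called in the fit without germ-free 1 and in no other fit with 1 library left out. The stromal covariate ended both calls in edgeR, with 2 at an unadjusted p under 0.05, a median absolute log2 fold change of 0.66 before and 0.65 after, and a median SE of 0.149 and 0.241. Interferon-stimulated genes were also lower as lists by camera at the preset correlation, without any single call. For type I interferon 33 of 38 genes were below 0 (median −0.57, camera adjusted p = 1.58e-05; adjusted p = 0.588 with an estimated correlation, fry 0.409). For interferon gamma and guanylate-binding genes 14 of 17 were below 0 (median −0.57, adjusted p = 0.0203; adjusted p = 0.63 with an estimated correlation, fry 0.499), a camera call lost without SPF 3, SPF 4, germ-free 1 or germ-free 4. By edgeR both lists held 0 calls, over all genes and over the list alone, with 2 and 1 genes at an unadjusted p under 0.05. DESeq2 called 1 and 0 of them, with 4 and 3 at that p, and limma voom 0 and 0, with 12 and 5. Without germ-free 2 edgeR called 2 type I genes lower, with 11 and 4 at that p. The type I number was 4 without SPF 5 or germ-free 1 and 1 without SPF 4, and the interferon gamma number 2 without SPF 1, SPF 5 or germ-free 1 and 0 without germ-free 3.

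Several immune genes of epithelial cells fell in germ-free mice. Il1rn, the interleukin-1 receptor antagonist (ENSMUSG00000026981, chromosome 2, 24336853 to 24351494, plus strand), fell from 50.6 ± 6.44 to 24.5 ± 2.11 CPM (−1.05 ± 0.12, adjusted p = 0.00051). The chemokine gene Cxcl14 fell by 1.81 ± 0.27, Il34, a ligand of the CSF1 receptor, by 2.01 ± 0.51 and Ccl2 by 2.51 ± 0.60, while the chemokine gene Cx3cl1 rose by 0.89 ± 0.22. In all 4 of 26 cytokine and chemokine genes fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.013, lower, lost without SPF 4 or germ-free 1; adjusted p = 0.536 with an estimated correlation, fry 0.194). Among pattern recognition receptors and their adaptors 3 of 26 fell, with the same count adjusted over the list alone. These were Nod2, a sensor of bacterial muramyl dipeptide (−0.74 ± 0.15), Casp4, an inflammatory caspase that binds lipopolysaccharide (−0.85 ± 0.22), and Gsdmc, a gasdermin (−1.17 ± 0.25). That list was lower by camera (adjusted p = 0.012; adjusted p = 0.203 with an estimated correlation; fry 0.00211). Of 13 IL-17 and IL-22 response genes 2 fell (4 fell and 1 rose when adjusted over the list alone). Steap4, an IL-17-inducible metalloreductase (ENSMUSG00000012428, chromosome 5, 7960457 to 7982213, plus strand), fell from 29.4 ± 5.79 to 7.24 ± 3.20 CPM (−2.02 ± 0.28, adjusted p = 0.00334), and Stat3 fell by 0.30 ± 0.07. The list was lower by camera (adjusted p = 0.00989; adjusted p = 0.238 with an estimated correlation; fry 0.0224). Pglyrp4, a peptidoglycan recognition protein, fell from 1.25 ± 0.53 to 0.0741 ± 0.0132 CPM and was the single call among 11 tested antimicrobial and alarmin genes by edgeR, over all genes and over the list alone. Of the 38 genes in that list 27 were in the deposited table, so most were not tested. S100a8 and S100a9, whose counts are given at the end, were not tested either. The germ-free mean of Pglyrp4 lies below a floor of 3 counts, which is 0.192 to 0.279 CPM per germ-free library. The size of the Pglyrp4 fall and the germ-free SD are therefore uncertain. Without SPF 1, 2 of 15 tested antimicrobial genes fell. DESeq2 called 0 of the 11, with 1 at an unadjusted p under 0.05, and gave Pglyrp4 no adjusted p, and limma voom called 1. Spon2, a secreted matrix protein that can bind bacterial surfaces (ENSMUSG00000037379, chromosome 5, 33198184 to 33218455, minus strand), fell from 43.4 ± 8.65 to 12.9 ± 1.29 CPM (−1.76 ± 0.16, adjusted p = 8.09e-05). No NF-kB feedback gene was called by edgeR (0 of 22, 5 at an unadjusted p under 0.05; 1 higher and 1 lower adjusted over the list alone) or limma voom, DESeq2 called 1 higher and 1 lower, and camera gave an adjusted p of 0.0562. Without SPF 1 edgeR called 2 NF-kB genes lower, with 9 at an unadjusted p under 0.05, a number that was 2 without germ-free 1 and 3 without germ-free 3. The pattern recognition count was 0 without germ-free 3 and 1 without SPF 3, SPF 4, SPF 5, germ-free 1, germ-free 2 or germ-free 4. The cytokine count of falls was 2 without any library other than SPF 1 and germ-free 4, and the Cx3cl1 call was kept without SPF 4 or germ-free 1 and lost without each of the others. The Ccl2 and Casp4 calls held without SPF 1 and ended without each of the others, the log2 fold change of Ccl2 was −1.895 without SPF 5, the call of Il34 held without germ-free 4, that of Stat3 without germ-free 2 and that of Gsdmc without SPF 1 or SPF 5. The Nod2 call ended without SPF 5 or germ-free 3. Under the stromal covariate edgeR called Steap4 and Spon2 alone of the genes named in this paragraph, 0 of the 5 cytokine genes (4 at an unadjusted p under 0.05; median SE 0.266 before and 0.457 after), 0 of the 3 pattern recognition genes (2; 0.217 and 0.334) and 0 of the antimicrobial genes, with Pglyrp4 under that p. Other large falls were those of Clec2g, a lectin (−2.29 ± 0.48), Atp6v1c2, a proton pump subunit (−2.20 ± 0.51), Serpina3h, annotated as a transcribed pseudogene and close to other serpin genes (−1.99 ± 0.51), and the heparanase gene Hpse (−1.88 ± 0.36). These calls ended without SPF 5 or germ-free 3 (Clec2g), without SPF 4, SPF 5, germ-free 2 or germ-free 4 (Atp6v1c2), without any library other than SPF 1 and germ-free 3 (Serpina3h) and without SPF 4 (Hpse).

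The structural programme of the epithelium differed in single genes more than in lists. Of 20 basal keratinocyte genes 2 rose and 2 fell (4 and 3 when adjusted over the list alone). Dst, the gene of the hemidesmosome plakin BPAG1 (ENSMUSG00000026131, chromosome 1, 33908225 to 34308661, plus strand), rose from 3762 ± 468 to 6995 ± 450.1 CPM (0.89 ± 0.10, adjusted p = 0.00051). The laminin-332 chain gene Lama3 rose by 0.41 ± 0.09, and Igfbp3 (−0.59 ± 0.11) and Ptn (−0.44 ± 0.11) fell. Periplakin, Ppl, rose from 502 ± 89.1 to 841 ± 83.4 CPM (0.74 ± 0.12), while involucrin, Ivl (−1.37 ± 0.35), and Sprr2a3 (−2.57 ± 0.54) fell, the 3 calls among 23 cornified envelope genes over all genes and over the list alone. Sprr2a3 has near-identical neighbours in its gene cluster, so its counts are uncertain. Krt6b, a keratin of activated epithelium, fell from 73.0 ± 18.8 to 27.7 ± 8.43 CPM (−1.39 ± 0.24) as the 1 call among 14 suprabasal keratins, over all genes and over the list alone. P-cadherin, Cdh3, fell by 0.82 ± 0.16 as the 1 call among 22 desmosome and adherens junction genes by either adjustment, and 0 of 19 tight junction genes were called by either, with 4 at an unadjusted p under 0.05 and 1 called lower by DESeq2 and by limma voom, and by edgeR 2 lower without SPF 1 and 1 without germ-free 3. Of 15 wound-associated genes 2 fell by either adjustment, Krt6b and the urokinase gene Plau (−0.67 ± 0.11). None of these 6 lists was called by camera, with adjusted p-values of 0.636 (basal), 0.21 (suprabasal), 0.636 (cornified envelope), 0.555 (tight junction), 0.079 (desmosome) and 0.0916 (wound). Camera gave the basal list as higher with a median of 0.06 and a mean of −0.02, and the cornified envelope list as higher with a median of 0.09 and a mean of −0.08. Leaving out 1 library ended the Krt6b call without SPF 3, SPF 4, germ-free 2 or germ-free 4, the Cdh3 call without SPF 3, SPF 4, SPF 5 or germ-free 3, and the Ivl call without any library other than germ-free 1. The Sprr2a3 call held without SPF 1 or SPF 5 and ended without each of the others, the Lama3 call ended without SPF 3, SPF 5 or germ-free 4, and the Ptn call held without SPF 1 or germ-free 1 and ended without each of the others. Without SPF 1, 2 suprabasal keratins fell, and without SPF 5, 1 junction gene of the desmosome list rose. The stromal covariate ended each edgeR call of a gene named in this paragraph, with a median SE of 0.106 before and 0.172 after for the 4 basal genes and 0.354 and 0.601 for the 3 cornified envelope genes, of which 3 and 3 had an unadjusted p under 0.05 by edgeR.

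Vascular and connective tissue transcripts were higher in the germ-free sorts, at levels between a few counts (Emcn) and 267 CPM (Col3a1 in germ-free 3). Of 15 endothelial and mural genes 2 rose over all genes tested and 4 when adjusted over the list alone (median 2.103, camera adjusted p = 4.98e-05; adjusted p = 0.298 with an estimated correlation; fry 0.0937). Tie1, an endothelial receptor kinase, rose from 0.27 ± 0.19 to 4.58 ± 4.07 CPM. Its SPF mean lies at the floor of 3 counts, which is 0.205 to 0.305 CPM per SPF library, so the size of the rise is uncertain. Emcn, an endothelial sialomucin, had 1 count over the SPF group and 114 over the germ-free group, a ratio of 106 (95% counting interval 18.6 to 4222). Mmrn1, made by lymphatic endothelium and platelets (ENSMUSG00000054641, chromosome 6, 60924976 to 60989378, plus strand), had 2 counts against 400, a ratio of 186 (51.1 to 1540). The intervals cover counting error only, and the endothelial median is the value of Vwf and is the same with Emcn at the lower end of its interval. Of the 12 genes with the largest rises, Fabp4, of fat cells and capillaries, Tnxb, a connective tissue glycoprotein, Jam2, an endothelial adhesion molecule, and Prg4, lubricin, rose by 4.83 ± 1.05, 3.81 ± 0.69, 3.77 ± 0.86 and 3.41 ± 0.63 on the log2 scale. Slc43a3 (5.47 ± 1.06), Cyp2t4 (4.77 ± 0.71), Prex2 (4.47 ± 1.01), Sohlh1 (4.44 ± 0.85) and Coro2b (3.18 ± 0.63) completed the 12 with Dbp. Slc43a3 had 3 SPF counts without SPF 4 and 1 without SPF 3, so the size of its rise is uncertain too. Fibroblast genes had a median log2 fold change of 2.73 (camera adjusted p = 0.00989; adjusted p = 0.588 with an estimated correlation, fry 0.409), yet edgeR called 0 of the 13 higher, DESeq2 3 and limma voom 0, with 7 at an unadjusted p under 0.05 in either direction by edgeR (2 without SPF 1 or SPF 5, 3 without SPF 3) and 1 by limma voom. Thy1 fell by 0.70 ± 0.17 as the 1 call by either adjustment, held without germ-free 2 and lost without each of the others. Col1a1 was at 82.1 CPM in germ-free 3, between 5.59 and 9.63 CPM in the other germ-free libraries and at most 4.28 CPM in SPF libraries. Col3a1 was at 267 CPM in germ-free 3 and between 3.82 and 27.3 CPM in the other germ-free libraries. In SPF 4 it was at 18.6 CPM, and in the other SPF libraries at most 0.821 CPM. The mean log2 CPM of the fibroblast list was higher in SPF 4 (2.962) than in germ-free 1 (2.674). Without germ-free 3 the medians were 1.56 for fibroblast and 1.24 for endothelial genes. The Fabp4, Jam2, Prex2 and Tnxb calls each ended without any 1 SPF library, those of Fabp4, Jam2 and Prex2 also without germ-free 2, that of Jam2 without germ-free 3, and those of Fabp4 and Tnxb without germ-free 4. Without germ-free 3 the log2 fold changes were 4.14 for Slc43a3, 3.37 for Tie1, 3.31 for Prex2, 3.25 for Fabp4, 2.99 for Tnxb and 2.55 for Jam2. The Mmrn1 ratio was 74.6 (20.2 to 623) without germ-free 3 and 301 (53.6 to 11900) without SPF 1. Leaving out an SPF library gave 5.06 for Prex2 (SPF 1) and 5.58 for Cyp2t4 (SPF 3). Without SPF 1 the ratio for Sohlh1 was 75.9 (20.7 to 631, 2 SPF counts), without SPF 3 that for Slc43a3 was 150 (26.7 to 5960, 1 SPF count), and without SPF 5 Emcn had 0 SPF counts and was at least 25.9-fold higher against a floor of 3 counts over the group. None of these 7 genes that moved without germ-free 3 was called by limma voom, and DESeq2 gave Fabp4 no p. The Tie1 call ended without SPF 5, Slc43a3 without SPF 4 or SPF 5, Sohlh1 without SPF 3 and Prg4 without SPF 4. The stromal covariate, built from these lists, ended each edgeR call of a gene named in this paragraph.

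Other lists moved little or held few calls. The list of Wnt, Notch and Hedgehog targets (median 0.19, adjusted p = 0.0203; adjusted p = 0.262 with an estimated correlation, fry 0.0676), that of mechano- and sensory ion channels (0.31, adjusted p = 0.0428; adjusted p = 0.262 with an estimated correlation, fry 0.0668) and that of the TAM receptor axis (0.33, adjusted p = 0.0486; adjusted p = 0.262 with an estimated correlation, fry 0.0676) were higher by camera. In these 3 lists edgeR called 0 genes over all genes and 0, 3 and 2 higher adjusted over the list alone, with 3, 6 and 2 at an unadjusted p under 0.05, DESeq2 called 1, 0 and 1 higher and limma voom 1, 0 and 0. Without SPF 1 edgeR called 1, 1 and 0 higher, with 5, 5 and 2 at that p. The calls ended without SPF 3 (Wnt), without SPF 3, SPF 4, germ-free 1, germ-free 2 or germ-free 3 (ion channels) and without SPF 3, SPF 4, SPF 5, germ-free 2 or germ-free 3 (TAM). The unfolded protein response was lower by camera (median −0.25, adjusted p = 0.0259; adjusted p = 0.63 with an estimated correlation, fry 0.435), a camera call lost without SPF 4, SPF 5 or germ-free 1. In it Xbp1, a transcription factor that also stands in the plasma cell list, fell by 0.51 ± 0.12 as 1 of 26 genes (5 lower and 1 higher adjusted over the list alone), a count that was 9 without SPF 1 and 0 without SPF 4, SPF 5, germ-free 2, germ-free 3 or germ-free 4, while 1 rose without germ-free 1. In the same list DESeq2 called 6 lower and 1 higher, and limma voom 5 lower and 1 higher. Aldh3a1, an aldehyde dehydrogenase, rose by 0.51 ± 0.12 as 1 of 10 aryl hydrocarbon receptor targets (1 higher and 2 lower adjusted over the list alone), a call lost without SPF 4, SPF 5, germ-free 1, germ-free 3 or germ-free 4, and 1 fell without germ-free 1. The Xbp1, Aldh3a1 and Mbp calls also ended under the stromal covariate. Of 24 NRF2 and glutathione genes edgeR called 0 (5 lower adjusted over the list alone, 7 at an unadjusted p under 0.05), DESeq2 3 and limma voom 1. Camera gave 0.741 and 0.124 for these 2 lists, the first as higher with a median of 0.04 and a mean of −0.05. It gave 0.915 for the antimicrobial list, as lower with a median of 0.08 and a mean of 0.02, and 0.957 for skeletal muscle, in which edgeR, DESeq2 and limma voom called 0 of 6 genes and 0 had an unadjusted p under 0.05 (1 by edgeR without SPF 4, germ-free 1 or germ-free 4). It gave 0.555 for the melanocyte, Merkel and Schwann list, in which Mbp rose by 0.44 ± 0.11 as 1 of 8 genes by either adjustment, a call held without germ-free 3 and lost without each of the others. Leukocyte, B cell, T cell, neutrophil, salivary, taste, erythroid and MHC class II lists had under 5 tested genes each and no list test.

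Measures of RNA handling stood beside these groups as follows. All 36 cytosolic ribosomal protein genes were below 0, with 0 called by edgeR over all genes or over the list alone, 2 by DESeq2 and 1 by limma voom (median −0.22, camera adjusted p = 1.12e-11; adjusted p = 0.473 with an estimated correlation, fry 0.15). By edgeR 21 had an unadjusted p under 0.05, 5 without SPF 1 or germ-free 2 and 13 without SPF 4 or germ-free 4, and 30 by DESeq2 and 10 by limma voom. Of 31 genes induced by tissue dissociation 0 were called by edgeR, DESeq2 or limma voom, with 2, 5 and 2 at an unadjusted p under 0.05. By edgeR 2 were called higher without germ-free 1, with 7 at that p, a number that was 5 without SPF 4, 1 without SPF 1, SPF 3 or germ-free 3 and 0 without germ-free 4. The list was higher by camera (median 0.23, adjusted p = 0.0126; adjusted p = 0.678 with an estimated correlation, fry 0.539), a camera call lost without SPF 1, germ-free 3 or germ-free 4. Mitochondrially encoded genes took 1.11% of counts in SPF 1, 1.56% in germ-free 1 and 1.40% in germ-free 2, and 0.53% to 0.74% in the others (camera adjusted p = 0.103), and nuclear retained and structural RNAs gave 0.116. SPF 1 lay at −71.6 on the first principal component, which held 31.0% of the variance, with the other libraries between −19.3 and 44.6. Without SPF 1 and germ-free 3 together, a choice made after the data were seen, 419 genes were called, among them 11 clock genes higher and 3 lower, 15 cell cycle genes lower and 6 glycolysis genes lower.

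**Figure D4:**
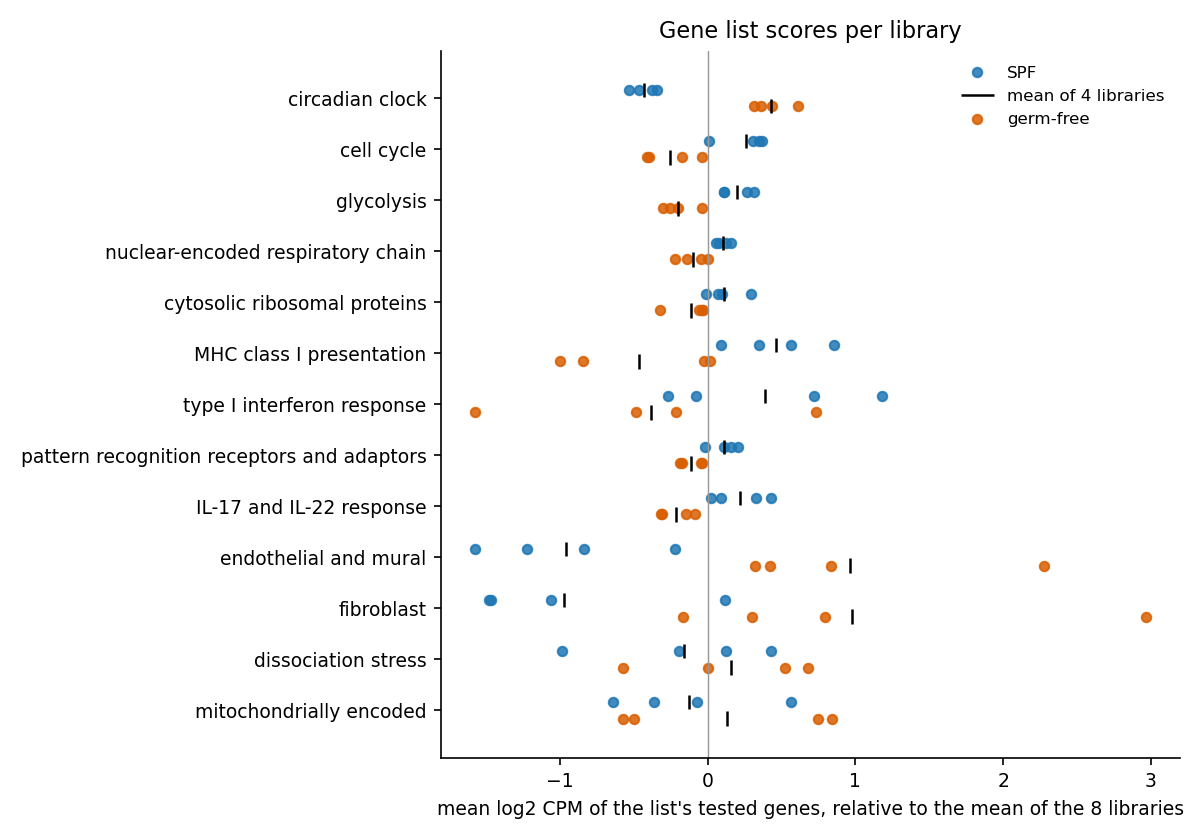
Mean log2 CPM of the tested genes of 13 lists in each library, relative to the mean of the 8 libraries, for SPF (blue) and germ-free (orange) mice, with black bars at the mean of each group. The type I interferon, fibroblast, dissociation stress and mitochondrial scores overlap between the groups. The scores of the other lists shown, the ribosomal protein list among them, do not. Germ-free 3 has the highest endothelial and fibroblast scores.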

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

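The tests of the 3 patterns weighed here were chosen only after the results were seen, and the comparison with other splits of the libraries was planned. In 24 of 404 groups of 4 libraries, 1 library stood farther from the others than Dixon's 95% critical value for 4 samples allows. Chance gives this in about 1 in 20 groups, or 20.2 here. Each value below is the gap of that library to its nearest neighbour as a share of the group's range in log2 CPM.

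Germ-free 3 was highest for Fabp4 (0.84; 24.1 CPM against 2.13 to 3.17), Tnxb (0.9; 118 against 27.2 to 31.5) and Krt24 (0.9; 89.8 against 43.9 to 47.2). Germ-free 2 was lowest for Cyp2t4 (0.906; 1.32 CPM against 8.27 to 10), Mgst1 (0.927), Rpl6 (0.864), Tnni2 (0.878) and the mean of the ribosomal protein list (0.912). Germ-free 4 was lowest for Sprr2a3 (0.878), and germ-free 1 was highest for Cd74 (0.838). SPF 5 was lowest for Arntl (0.877; 80.8 CPM against 104 to 108) and Hbb-bs (0.93) and highest for Cxcl14 (0.866; 115 CPM against 52.7 to 58.6). SPF 4 was highest for Bst2 (0.84) and Psme2 (0.873), and SPF 3 was lowest for Mvk (0.841) and Cx3cr1 (0.878). SPF 1 was highest for Ugt1a7c (0.841) and Mgst1 (0.928). It was lowest for Piezo2 (0.835), Nr4a2 (0.874), Meg3 (0.847), Mitf (0.907) and the mean of the melanocyte, Merkel and Schwann list (0.944).

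The number of genes called was highest in the real grouping. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many genes as the 631 called, as the 279 higher and as the 352 lower, and the highest of the other splits was 0 in each case. That share of 1 in 35 is the smallest this comparison can give. The other splits mix the groups, so any difference between the groups adds to their spread and lowers their counts. The comparison argues against chance at that share and cannot exclude it. For the 20 lists called chance cannot be excluded, since 3 of the 35 splits gave as many and the highest other gave 21.

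Clock activators were lower and clock repressors and output genes higher in germ-free libraries. Stromal and vascular RNA as the whole cause was argued against for Bhlhe41 and Per3, which stayed called at log2 fold changes of 2.69 and 2.99 with the stromal score as covariate, and for the other 11 called clock genes, whose median absolute log2 fold change went from 1.44 (median SE 0.186) to 1.25 (0.305) with 11 at an unadjusted p under 0.05 by edgeR and 0 called, as the SE rose with a score that correlates with the group (r 0.775). Stress during digestion was argued against as the whole cause, since with the dissociation score, which correlated with the group at r 0.296, as covariate the 13 called clock genes stayed called by edgeR, at a median absolute log2 fold change of 1.87 (median SE 0.186) before and 1.80 (0.182) after. A different hour of tissue collection cannot be told apart from an effect of the microbiota, since 0 of the 13 genes moved with the other arm, a shifted clock would give this from either cause, and the labels give no hour. An effect of the microbiota may therefore explain the pattern but remains untested. No batch is given either, so a batch following the groups cannot be told apart from such an effect, for this pattern or those below.

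Endothelial and fibroblast markers were higher in germ-free libraries although the cells were sorted as epithelium. Germ-free 3 alone was argued against as the cause, since the medians without it were 1.24 for the endothelial list and 1.56 for the fibroblast list. More stromal and vascular cells or their RNA in the germ-free sorts cannot be told apart from a difference in the tissue itself, which stays open as untested, since the 92.9% of the 28 tested members above 0 restate the pattern.

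MHC class I genes were lower in germ-free libraries. A single library was argued against as the cause, since the median of the list was −0.652 or lower whichever library was left out. RNA quality was argued against only as read from mitochondrial genes, since the median was −1.01 with that score as covariate. The mitochondrial score overlapped between the groups. The ribosomal protein score did not overlap and was not used as covariate, so RNA quality as read from it stays untested. Reads shared between heavy chains were argued against, since the 13 members that are no heavy chain had a median of −0.618 (−0.404 without SPF 4). The summed CPM of 15 tested heavy chains and related genes was 0.532 of that in SPF libraries, without overlap. Within groups the class I and type I interferon scores correlated over 8 libraries (Pearson r 0.881, exact within-group permutation p = 0.00174; Spearman rho 0.857, exact permutation p = 0.00347; r 0.782 without the 2 libraries farthest from the median). That link does not address the difference between the groups, and no fit with the interferon score as covariate was run. Germ-free 2 had a type I score (3.919) above SPF 1, 3 and 5 (3.103, 3.903 and 2.912) but a lower class I score (6.041 against 6.374, 6.586 and 6.113). That library also held the most RNA of the leukocyte gene Ptprc (13.1 CPM, against at most 1.6 CPM in SPF libraries). Whether leukocyte RNA bears on its scores was not tested. Type I scores of germ-free 3 and 4 (2.699 and 1.606) lay below every SPF library, and that of germ-free 1 (2.968) above SPF 5 alone. A lower interferon response therefore stays open as a cause. An effect of the microbiota stays open as untested.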

How the results depend on the processing

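The fit with a stromal score and the fit without SPF 1 and germ-free 3 together were chosen only after the results were seen, and the other alternatives were planned. No called gene reversed its sign under any alternative run. The genes called (631), the genes higher in germ-free (279) and the genes lower in germ-free (352) stayed within 1.5 times under DESeq2 size factors (626), upper-quartile factors (659), no filter (554) and a filter of 10 counts in 4 libraries (612). The DESeq2 Wald test called 1257 (598 higher, 659 lower) and limma voom with quality weights 1023 (455 and 568), with 627 and 605 of the 631 among them, and the cause was not tested. A bound of 1 on the absolute log2 fold change left 189 (83 and 106), and an adjusted p under 0.1 gave 1191 (564 and 627), by construction. With 1 library left out the calls ranged from 284 to 688, the higher from 128 to 286 and the lower from 152 to 402, with fewer samples in each fit. Without SPF 1 and germ-free 3 together 419 were called (187 higher, 232 lower). With the stromal score as covariate 12 were called (8 higher, 4 lower), as the median absolute log2 fold change of the 631 genes went from 0.725 to 0.671 and the median SE from 0.138 to 0.217, the score differing between the groups. A replicate block over numbers 1, 3 and 4 called 315 (156 and 159). Nothing in the labels ties same-numbered animals of the groups, so the numbers were not taken to pair animals. Deviations of same-numbered libraries correlated across genes at 0.16, −0.0558 and −0.0457. The SPF libraries are numbered 1, 3, 4 and 5 in the titles, which are the numbers used here, but 1 to 4 in the source names. Numbered by the latter, the correlations were 0.16, 0.118, 0.122 and 0.067, and no block was fitted by these numbers. Libraries of unlike number were not compared, so the correlations do not decide whether animals were paired. The 20 lists called became 0 with an estimated correlation and 6 by fry, 24 without a filter and 16 with the block, and ranged from 16 to 25 with 1 library left out. Of the 63 called named genes 35 lost the call without some library and 4 were called under every alternative. Of the 63, 59 were not called with the stromal score as covariate (all but Bhlhe41, Per3, Spon2 and Steap4), 34 with the replicate block, 22 without SPF 1 and germ-free 3 together and 12 to 29 with 1 library left out, 29 of them without SPF 4. Limma voom did not call 14 (Mmrn1, Tnxb, Sprr2a3, Prex2, Tie1, Slc43a3, Jam2, Atp6v1c2, Ccl2, Fabp5, Pnpla1, Casp4, Mbp and Fabp4), the fit with no filter 8 (Tnxb, Sprr2a3, Gsdmc, Prex2, H2-D1, Il34, Mbp and Fabp4) and the filter of 10 counts in 4 libraries Mbp, while Emcn was not tested under it. DESeq2 gave no adjusted p for Pglyrp4 and Fabp4 and called the other 61.

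Named genes that reversed were all uncalled, 15 in number, and the cause was not tested. With the replicate block Krt76 was at 0.0852 and Mb at −0.0135, and with limma voom Hbb-bs was at 0.0246. With the stromal score as covariate Lyz2 was at −0.78, Meg3 at −0.18, Kit at −0.14, Ttn at −0.50, Krt7 at −0.12, Krt19 at −0.20, Krt18 at −1.09 and Krt8 at −1.18. Without SPF 1 and germ-free 3 together Krt18 was at −0.37 and Krt8 at −0.43. With 1 library left out the Cx3cr1 log2 fold change ranged from −0.07126 to 0.33, the Tnni2 log2 fold change from −0.33 to 0.006246, Wfdc18 from −0.65 to 3.17, Krt18 from −0.26 to 0.98, Krt8 from −0.29 to 0.98 and Krt20 from −1.58 to 0.16. Depth limited genes of 1 to 3 counts in a group, as for Mmrn1 and Emcn.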

Other observations

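The genes and families below were chosen only after their values were seen. Of 56 tested histone genes 55 had a log2 fold change below 0 (median −0.87, −1.08 to −0.76 with 1 library left out), and 17 fell and 0 rose by edgeR. The 22 mitotic members of the cell cycle list were all below 0 (median −1.12) and Mcm2 to Mcm7 all above 0 (median 0.68), with TMM, DESeq2 and upper-quartile factors alike. Among gene ontology terms in the deposited table, rhythmic process held 13 of 116 genes called higher (adjusted p = 0.0031), and cell division held 47 of 335 called lower (adjusted p = 6.86e-16).

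The taurine transporter gene Slc6a6 rose from 655 to 1375 CPM (1.07 ± 0.09, adjusted p = 7.26e-05) and the cyclin gene Ccnd2 from 338 to 935 CPM (1.47 ± 0.13), while the connexin gene Gja1 fell from 1148 to 557 CPM (−1.04 ± 0.09). S100a8, a subunit of calprotectin, had 0, 11, 133 and 133 counts in SPF 1, 3, 4 and 5 and 0 in each germ-free library, and S100a9 had 3, 47, 258 and 159 against 1, 0, 0 and 0. Neither was tested, and a count of 0 allows up to 0.192 to 0.279 CPM per germ-free library at a floor of 3 counts. Gm47283, annotated on chromosome Y, lay between 4.72 and 10.8 CPM in SPF and between 61.5 and 128 CPM in germ-free libraries (3.57 ± 0.31, adjusted p = 0.00118). Xist was high and the Y-linked Kdm5d low in every library, so this gap was not read as a difference in sex. Mid1 was at 96.9 CPM in germ-free 2 and 157 CPM in germ-free 4, and between 26.5 and 38.2 CPM in the others. The salivary mucin gene Muc5b reached 158 CPM in germ-free 4 and 27 CPM in SPF 4. The leukocyte gene Ptprc was at 13.1 CPM in germ-free 2 and at most 1.6 CPM in SPF libraries. Krt1 reached 2470 CPM in an SPF library and 1480 CPM in a germ-free library.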
